A study of Mus musculus with 12 samples.

How the data were processed

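DCs were taken from individual mouse spleens by positive selection, and RNA was purified on RNeasy columns and checked on a Bioanalyzer, per the labels' protocols. RNA was amplified with WT-Ovation Pico, which primes with oligo(dT) and random primers, labelled with biotin and hybridised to Affymetrix arrays. Wild-type (WT) and miR-142 knockout (KO) littermates were matched for age and sex, and cells were unstimulated or given lipopolysaccharide (LPS), whose dose and duration are not given in the sources used here. The sample titles, sources and cell type fields name DCs while the sample descriptions name T cells, and the samples were taken as DCs. Per the submitters' processing notes the authors normalised the arrays with RMA, and the deposited values are log2 signals. The RMA software version is not given in the sources used here. Array medians ran from 2.65 to 2.72 on the log2 scale, and no pair of arrays was identical (closest pair WT unstimulated 1 and WT LPS 1, SD of the difference 0.227).

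The table held 45141 probe sets. The 104 control probe sets, the 551 with several gene symbols and the 15588 without a symbol in the table used here were left out of the gene tests, and the 28898 with 1 symbol were kept, of which 28689 matched a RefSeq gene by Entrez number. Where a gene had more than 1 probe set (7180 genes) the probe set with the highest mean over the 12 arrays was used, giving 17097 genes. No filter on dim genes was applied. Probe sets without a single symbol were tested in the same way and are counted only in the closing section.

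All comparisons came from 1 linear model with 4 group means of 3 arrays each, fitted with limma 3.58.1 in R 4.3.3 with lmFit and eBayes at default settings (8 residual degrees of freedom, prior 4.31, moderated total 12.3). The 6 contrasts were KO versus WT unstimulated, KO versus WT after LPS, LPS versus unstimulated in WT and in KO, KO versus WT averaged over both stimulations, and the LPS effect in KO minus that in WT. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast were called. Errors printed after ± are moderated SEs of the log2 fold change. Overlaps between comparisons were set against the count expected from independent calls.

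The 27 gene lists were glycolysis, oxidative phosphorylation, fatty acid oxidation, TCA cycle, hypoxia, inflammatory cytokines, NF-kB feedback, type I interferon, DC maturation, MHC class II, MHC class I, cDC1, cDC2, plasmacytoid DC, T cell, B cell and plasma cell, NK cell, macrophage and monocyte, neutrophil, erythroid, platelet, cell cycle, proposed miR-142 targets, immediate early and stress, cholesterol synthesis, NRF2 antioxidant and actin cytoskeleton genes. They were written from general knowledge of the field and not chosen on these samples, and 535 of 614 members were measured. The comparisons, lists, threshold and the alternatives other than the random block, the pair means, list tests by pair and fits combining a block or an estimated correlation with leaving out an array were set before the data were examined. Each list was tested in each contrast with camera (limma) at an inter-gene correlation of 0.01, adjusted over all 162 tests, and again with an estimated correlation and with fry. Members were counted as called over all genes and again adjusted over the list alone.

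Genes were named by a rule. In each contrast these were up to 8 of the largest rises and 8 of the largest falls among called genes whose 3 arrays of one group all lay above the 3 of the other (within each stimulation for the averaged comparison, and without this condition for the difference), which chance gives for 10% of genes in a comparison of 3 with 3 arrays and for at most 10% in the averaged one. Predicted gene models, small RNAs and genes whose higher group mean lay under the median gene were not named this way. Up to 3 called members per list with the largest change, and up to 2 members that did not pass, were named as examples. Cpt1a, E2f7, E2f8, Il6 and Il12b were named throughout.

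The labels give each sample its own mouse number within genotype and stimulation, so they do not say whether the unstimulated and LPS arrays of one number share a mouse. After group means were removed, same-numbered arrays within a genotype correlated at 0.385, 0.230 and 0.422 in WT and at 0.305, 0.284 and 0.440 in KO, while different numbers ran from −0.336 to −0.032. The negative values follow in part from removing group means and are not separate evidence of pairs. Across genotypes the same number gave −0.009, 0.091 and 0.221 unstimulated and 0.012, 0.090 and 0.189 after LPS. Same-numbered arrays within a genotype were therefore treated as pairs in named alternatives, as a fixed block, as a random block fitted with duplicateCorrelation (statmod 1.5.0, consensus correlation 0.174) and as pair means. Numbers were paired across genotypes only in the alternative that blocked by array number over all arrays.

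The gene tests were tested on simulated data in 10 runs with 200 changed genes each. Of shifts of 0.5, 1 and 2, 24.6%, 88.8% and 99.7% were recovered for a comparison of 3 with 3 arrays, 66.6%, 97.6% and 99.8% for the averaged comparison and 5.97%, 61.3% and 98.0% for the difference of LPS effects, with 5.40%, 5.23% and 5.26% false calls. The simulated arrays were drawn independently, without the resemblance of same-numbered arrays, correlation between genes or an array that stood apart. Each run also held 200 changed genes, and with fewer true changes the adjusted threshold is harder to pass. These shares therefore need not hold for the real arrays, least of all for the averaged comparison, where same-numbered arrays were counted apart. The number of arrays, 3 per group, limits the precision.

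Alternatives covered filters on dim genes, a further quantile normalisation or median centring, other choices of probe set, trend and robust variance settings, array weights, fits to the groups of a contrast alone, other thresholds, blocks by array number and leaving out each array. Tests on genes with miR-142 seed sites were planned and not run, because no 3' UTR sequences were at hand. Mir142 itself had no single-symbol probe set. No array was left out of the model.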

Results

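Gene expression in dendritic cells (DCs) from mouse spleen was measured on 12 Affymetrix arrays, in miR-142 knockout (KO) and wild-type (WT) littermates, unstimulated or given lipopolysaccharide (LPS), with 3 arrays per group. The mice were 10-week-old C57BL/6 males, and each array came from the DCs of a single spleen taken by positive selection. The deposited log2 values covered 17097 genes after 1 probe set was kept per gene. The targeted gene, Mir142, had no probe set that carried its symbol alone, so its level was not analysed here and the genotype labels were not checked against it. Within each genotype the unstimulated and LPS arrays of the same number resembled each other after group means were removed. They correlated at 0.385, 0.230 and 0.422 in WT and 0.305, 0.284 and 0.440 in KO, while arrays of different numbers all correlated below 0. Values below 0 follow in part from removing group means, which makes the deviations within a group sum to 0. The KO and WT arrays of the same number correlated less, at −0.009, 0.091 and 0.221 unstimulated and 0.012, 0.090 and 0.189 after LPS. Number 3 thus came near the lowest value within a genotype, but numbers 1 and 2 did not. No pairs across genotypes were assumed, except in the alternative that blocked by array number over all arrays.

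Array 2 of the LPS-treated KO group stood apart from the other 11. Its correlations with them ran from 0.935 to 0.958, against 0.966 to 0.991 among the other pairs. Its Gapdh signal was 3.04 log2 units higher at the 3' end than in the middle of the transcript, against 1.53 to 1.86 on the other arrays, and the same gap for beta-actin was 0.94 against 0.02 to 0.16. Its MHC class I genes had a list median of −0.83 relative to the mean of the WT arrays, against −0.15 to 0.07 elsewhere, and its MHC class II median was −0.48 against −0.06 to 0.15. The array was kept, and each count is also given without it. The bioB hybridisation control differed between groups, with means of 8.88 in unstimulated WT, 8.30 in WT with LPS, 8.11 in unstimulated KO and 7.93 in KO with LPS (SD 0.19, 0.13, 0.28 and 0.47, n = 3 arrays each), so the mean of this technical signal was lower in KO and after LPS. Its arrays did not overlap between unstimulated genotypes or between WT with and without LPS, which chance gives in 10% of comparisons of 3 with 3 arrays, and overlapped in the other comparisons.

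**Figure D1:**
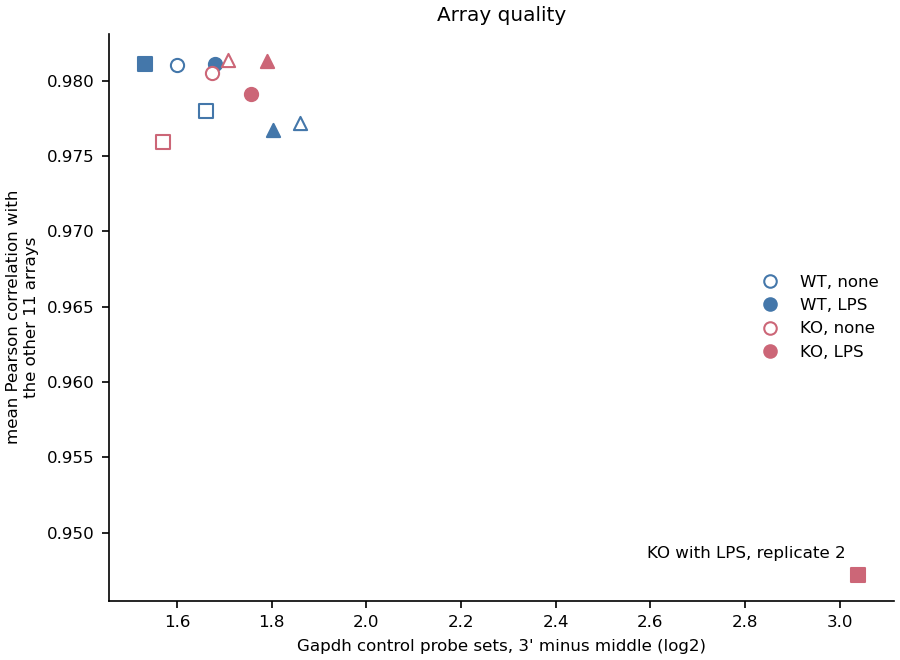
Gapdh signal at the 3' end minus the middle of the transcript against the mean correlation with the other 11 arrays, one point per array.

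Unstimulated KO arrays held more transcript of neutrophil granule genes and natural killer (NK) cell genes than WT arrays, and less of the antibody joining chain. Lcn2, which encodes the iron-scavenging protein lipocalin 2, rose by 5.72 ± 0.83 (log2 fold change ± SE, n = 3 arrays per group, limma adjusted p = 0.0195). The lower group mean of Lcn2, Chil3, Klra8, Gzmb, Acsl3 and Mmp12 lay under the median of all genes (3.14), at the dim end where fold sizes are less certain and are better read as minimum values. In later comparisons this also held for others, such as Adm, Ehf, Hmgn3, Rtl8c, Il6 and Ifnb1. Ngp (5.21 ± 0.75, adjusted p = 0.0195), Camp (5.15 ± 0.76, adjusted p = 0.0195), Chil3 (5.01 ± 0.77, adjusted p = 0.0237) and Chil4 (4.29 ± 0.69, adjusted p = 0.0248) rose with it. Klra8 and Klra9, which encode lectin-like receptors of NK cells, rose by 3.68 ± 0.36 (adjusted p = 0.0021) and 2.98 ± 0.26 (adjusted p = 0.00087). Jchain, which links antibody chains in plasma cells, fell by 4.03 ± 0.42 (adjusted p = 0.0023), and Mmp12, which encodes a macrophage elastase, fell by 2.23 ± 0.24 (adjusted p = 0.0023). Granzyme genes rose, with Gzmb at 2.34 ± 0.32 (adjusted p = 0.0173) and Gzma at 3.12 ± 0.56 (adjusted p = 0.0448). The fatty acid activating enzyme gene Acsl3 rose by 1.27 ± 0.17 (adjusted p = 0.0160) and the monocyte antigen gene Ly6c1 by 1.27 ± 0.22 (adjusted p = 0.0372). Among falling genes, Cxcl10 and Ccl4, which encode chemokines that draw T cells and monocytes, changed by −1.99 ± 0.28 (adjusted p = 0.0173) and −1.72 ± 0.27 (adjusted p = 0.0248). Stat4 (−1.34 ± 0.21, adjusted p = 0.0237), Rrad (−1.02 ± 0.14, adjusted p = 0.0179), Trim35 (−0.88 ± 0.13, adjusted p = 0.0195) and Nup54 (−0.63 ± 0.11, adjusted p = 0.0463) also fell.

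The neutrophil list rose as a whole in unstimulated KO arrays (median 3.17, camera adjusted p = 2.55e-21, adjusted p = 0.179 with an estimated correlation). Of its 14 measured members 4 were higher over all genes and 14 when adjusted over the list alone. The NK list rose by a median of 0.86, with 4 of 14 members higher, Klrb1b among them, and 10 adjusted over the list alone (camera adjusted p = 1.98e-15, adjusted p = 0.0438 with an estimated correlation, and 0.0817 with it and without KO LPS array 2). Platelet genes (10 measured, median 0.52) rose with 0 members past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.000737, adjusted p = 0.492 with an estimated correlation). Erythroid genes (11 measured, median 0.59) rose with 0 members past the threshold and 1 adjusted over the list alone (camera adjusted p = 0.00196, adjusted p = 0.567 with an estimated correlation). The macrophage and monocyte list (20 measured, median 0.37) rose with Ly6c1 as its 1 higher member, and with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0323, adjusted p = 0.745 with an estimated correlation).

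**Figure D2:**
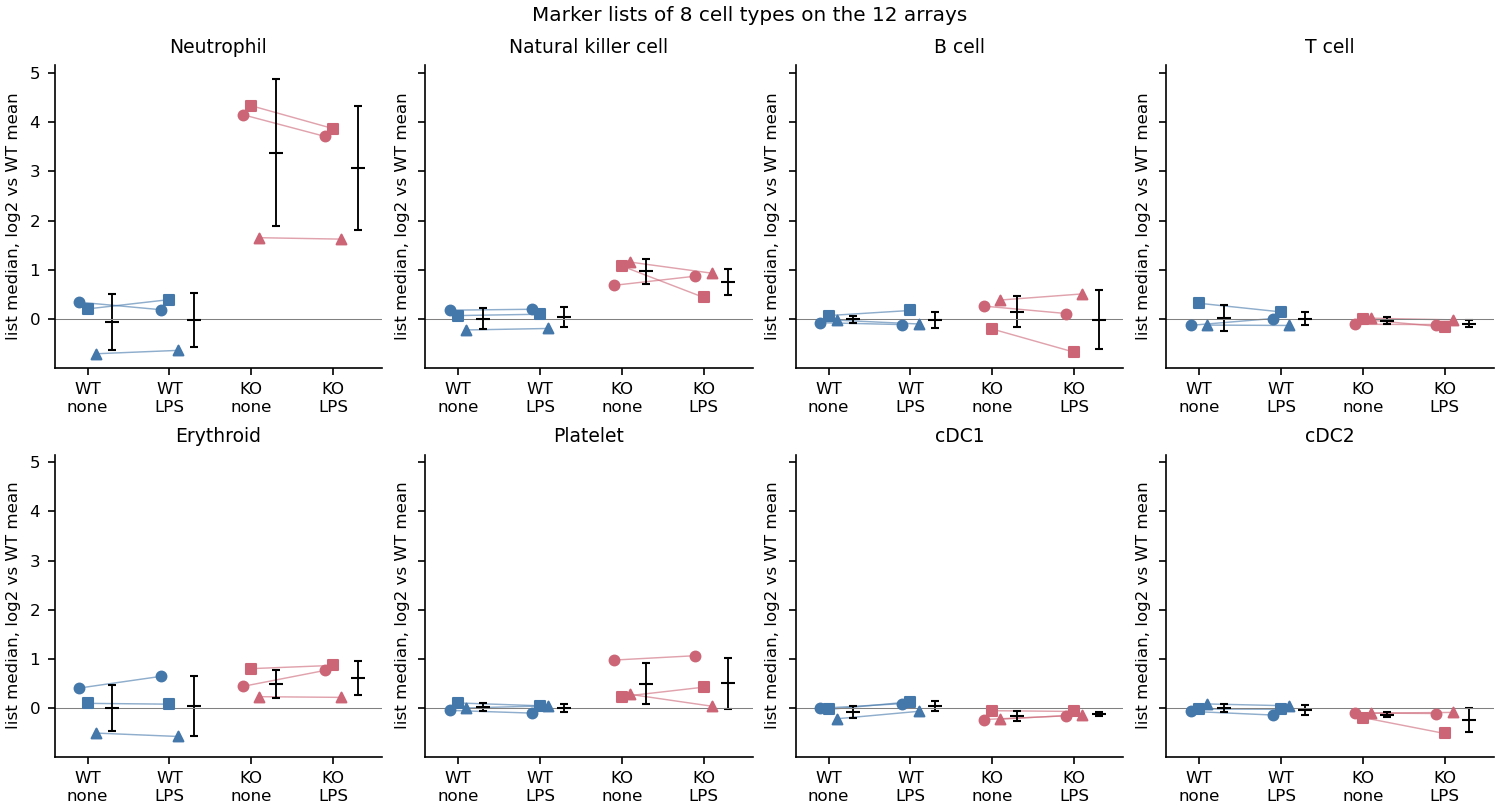
Median of 8 cell type gene lists on each array relative to the mean of the WT arrays, with lines joining same-numbered arrays and mean ± SD of 3 arrays.

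Inflammatory cytokine genes fell in unstimulated KO arrays (30 measured, median −0.19, camera adjusted p = 2.86e-05, adjusted p = 0.114 with an estimated correlation). Cxcl10 and Ccl4 were its 2 lower members and none was higher, with 8 lower adjusted over the list alone, while Il6 (0.12 ± 0.31, adjusted p = 0.967) and Il12b (−0.13 ± 0.16, adjusted p = 0.890) did not pass. NF-kB feedback genes (23 measured, median −0.17) fell with 0 members past the threshold and 1 lower adjusted over the list alone (camera adjusted p = 0.0075, adjusted p = 0.488 with an estimated correlation). Cholesterol synthesis genes (18 measured, median −0.19) fell with 0 members past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.0148, adjusted p = 0.481 with an estimated correlation). NRF2 antioxidant genes (19 measured, median 0.24) rose with 0 members past the threshold and 1 higher adjusted over the list alone (camera adjusted p = 0.000994, adjusted p = 0.488 with an estimated correlation). Proposed targets of miR-142 (26 measured, median 0.16) rose with 0 members past the threshold and 1 higher adjusted over the list alone (camera adjusted p = 0.00912, adjusted p = 0.179 with an estimated correlation). Oxidative phosphorylation genes (54 measured, median 0.10) rose with 0 members past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.0109, adjusted p = 0.696 with an estimated correlation). Fatty acid oxidation genes (21 measured, median 0.14) rose (camera adjusted p = 0.0292, adjusted p = 0.497 with an estimated correlation). Acsl3 was the 1 member past the threshold, over all genes and adjusted over the list alone, and Cpt1a (0.30 ± 0.25, adjusted p = 0.813) did not pass. Neutrophil markers, at a median of 3.17, were higher in the same KO arrays as each of these groups.

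The other 15 lists did not pass in unstimulated cells. Glycolysis genes had a median of 0.28 (camera adjusted p = 0.0502), TCA cycle genes 0.05 (adjusted p = 0.462) and hypoxia genes 0.12 (adjusted p = 0.124). Type I interferon genes had −0.06 (adjusted p = 0.297) and DC maturation genes −0.12 (adjusted p = 0.0671). Without array 2 of the LPS-treated KO group the hypoxia list rose (adjusted p = 0.0496, and adjusted p = 0.398 with an estimated correlation) and the DC maturation list fell (adjusted p = 0.0288, and adjusted p = 0.813 with an estimated correlation). MHC class II (median 0.06, adjusted p = 0.297), MHC class I (0.04, adjusted p = 0.981), cDC1 (−0.11, adjusted p = 0.0835), cDC2 (−0.05, adjusted p = 0.327) and plasmacytoid DC genes (0.14, adjusted p = 0.429) did not pass. T cell genes (−0.05, adjusted p = 0.638), cell cycle genes (0.05, adjusted p = 0.749), immediate early genes (−0.11, adjusted p = 0.0882) and actin cytoskeleton genes (0.07, adjusted p = 0.109) did not pass either. The B cell and plasma cell list (14 measured, adjusted p = 0.906) had a median of 0.20 and a mean of −0.18, opposite in sign because Jchain fell. The cell cycle regulators E2f7 (0.14 ± 0.13, adjusted p = 0.851) and E2f8 (0.23 ± 0.44, adjusted p = 0.951) did not pass. Both genes were dim, with unstimulated means of 1.84 in WT and 1.97 in KO for E2f7, and 2.68 and 2.91 for E2f8. Their group means lay under the median of all genes (3.14), except E2f8 in KO with LPS (3.57, array 2 at 4.88). A change could be missed at such levels, so here and in later comparisons the tests cannot decide whether either gene changed.

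In unstimulated cells limma called 43 genes at an adjusted p under 0.05, 35 higher and 8 lower in KO. The count was 16, 9 and 5 without WT unstimulated array 1, 2 or 3, 8 without KO unstimulated array 1 or 2, 78 without KO unstimulated array 3, 25 without WT LPS array 1 and 166 without KO LPS array 2. Jchain, Klra8, Klra9 and Mmp12 passed in every fit that left out 1 array. With 3 arrays per group, 24.6% of genes shifted by 0.5 and 88.8% of genes shifted by 1 in the self-test were recovered, so small changes were mostly missed.

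**Figure D3:**
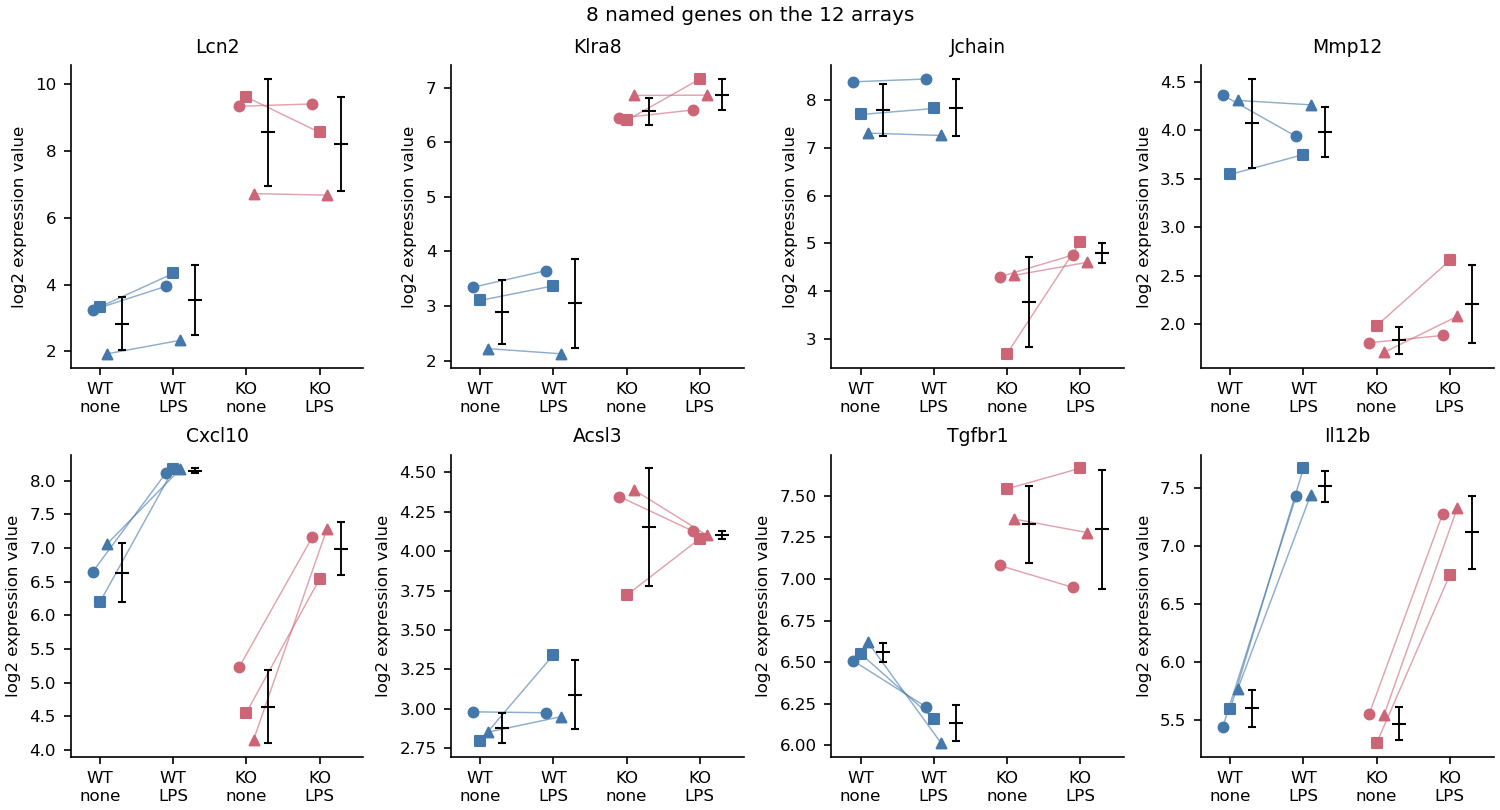
Log2 level of 8 genes on each array by genotype and stimulation, with mean ± SD of 3 arrays.

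After LPS the KO arrays again held more transcript of neutrophil and NK cell genes, and less of Jchain and the light chain genes Iglv1 and Igkv19-93. Chil3 (4.84 ± 0.77, limma adjusted p = 0.0216), Camp (4.83 ± 0.76, adjusted p = 0.0215) and Ngp (4.79 ± 0.75, adjusted p = 0.0215) rose (n = 3 arrays per group). Lcn2 (4.67 ± 0.83, adjusted p = 0.0322) and Chil4 (3.59 ± 0.69, adjusted p = 0.0462) rose with them. Klra8 rose by 3.82 ± 0.36 (adjusted p = 0.00137), and Klra9 by 2.82 ± 0.26 (adjusted p = 0.00137). Gzmb rose by 2.12 ± 0.32 (adjusted p = 0.0215) and Eomes, which encodes a transcription factor of NK cells, by 1.59 ± 0.25 (adjusted p = 0.0215). Tgfbr1, a TGF-beta receptor gene and proposed miR-142 target, rose by 1.16 ± 0.17 (adjusted p = 0.0195). The hypoxia-responsive genes Adm (1.08 ± 0.16, adjusted p = 0.0195) and Vegfa (0.78 ± 0.14, adjusted p = 0.0390) and the lipid gene Acsl3 (1.01 ± 0.17, adjusted p = 0.0240) rose. Jchain fell by 3.05 ± 0.42 (adjusted p = 0.0170), and the light chain genes Iglv1 (−2.39 ± 0.41, adjusted p = 0.0260) and Igkv19-93 (−2.16 ± 0.41, adjusted p = 0.0436) fell. Mmp12 (−1.77 ± 0.24, adjusted p = 0.0168), Ehf (−1.74 ± 0.27, adjusted p = 0.0215) and Stat4 (−1.26 ± 0.21, adjusted p = 0.0240) fell. Hmgn3 (−1.20 ± 0.19, adjusted p = 0.0215) and Rtl8c (−1.15 ± 0.19, adjusted p = 0.0254) fell as well. Xcr1, a chemokine receptor gene of cross-presenting cDC1 cells, fell by 0.78 ± 0.15 (adjusted p = 0.0494).

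Among lists after LPS, neutrophil genes rose by a median of 3.06, with 4 of 14 higher and 12 adjusted over the list alone (camera adjusted p = 1.88e-15, adjusted p = 0.242 with an estimated correlation). NK genes rose by a median of 0.90, with 4 of 14 higher, and 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.43e-09, adjusted p = 0.103 with an estimated correlation). Hypoxia genes (19 measured, median 0.27) rose with Adm and Vegfa as 2 higher members and 3 adjusted over the list alone (camera adjusted p = 0.00962, adjusted p = 0.187 with an estimated correlation). Their median was 0.15 without KO LPS array 2. Proposed miR-142 targets (median 0.22) rose with Tgfbr1 as 1 higher member and 2 adjusted over the list alone (camera adjusted p = 0.00405, adjusted p = 0.143 with an estimated correlation), and their median was 0.14 without that array. Fatty acid oxidation genes (median 0.17) rose with Acsl3 as 1 higher member and 3 adjusted over the list alone (camera adjusted p = 0.0058, adjusted p = 0.458 with an estimated correlation). Without KO LPS array 2 that list did not pass (median 0.019, adjusted p = 0.129). Platelet (median 0.50, camera adjusted p = 0.000994, adjusted p = 0.503 with an estimated correlation) and erythroid genes (median 0.58, camera adjusted p = 0.0178, adjusted p = 0.638 with an estimated correlation) rose. NRF2 genes (median 0.21, camera adjusted p = 0.0142, adjusted p = 0.584 with an estimated correlation) rose with 0 members past the threshold and 2 adjusted over the list alone. Oxidative phosphorylation genes (median 0.05, camera adjusted p = 0.0334, adjusted p = 0.798 with an estimated correlation) rose with 0 members past the threshold, and their median was 0.084 without that array. Neutrophil markers were higher in the same KO arrays as each of these groups.

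MHC class I genes fell in KO after LPS (14 measured, median −0.40, camera adjusted p = 0.000994, adjusted p = 0.481 with an estimated correlation), with 0 members past the threshold. Their median was −0.18 without KO LPS array 2 (adjusted p = 0.0087). The cDC1 list (16 measured, median −0.16) fell with Xcr1 as 1 lower member and 3 adjusted over the list alone (camera adjusted p = 0.0163, adjusted p = 0.481 with an estimated correlation). The cDC2 list (15 measured, median −0.22) fell with 0 members past the threshold and 4 lower adjusted over the list alone (camera adjusted p = 0.00822, adjusted p = 0.488 with an estimated correlation). It did not pass without KO LPS array 2 (median −0.06, adjusted p = 0.227). Type I interferon genes (28 measured, median −0.28) fell with 0 members past the threshold, and 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0178, adjusted p = 0.575 with an estimated correlation). Cholesterol synthesis genes (median −0.20) fell with 0 members past the threshold and 1 lower adjusted over the list alone (camera adjusted p = 0.020, adjusted p = 0.481 with an estimated correlation), and their median was −0.13 without that array. Cytokine genes (median −0.14, adjusted p = 0.201), NF-kB feedback genes (−0.15, adjusted p = 0.634, and −0.036 without KO LPS array 2) and glycolysis genes (0.00, adjusted p = 0.871, and 0.10 without it) did not pass. Il6 (0.83 ± 0.31, adjusted p = 0.271) and Il12b (−0.40 ± 0.16, adjusted p = 0.296) did not pass, with 0.41 and −0.21 without KO LPS array 2. Il6 passed in the fit without KO LPS array 3 (1.22, adjusted p = 0.0343). The same test was not passed by Cpt1a (0.61, adjusted p = 0.319), E2f7 (0.04, adjusted p = 0.917) or E2f8 (0.92, adjusted p = 0.376), with 0.41, −0.04 and 0.27 without KO LPS array 2. The B cell list did not pass (median −0.11, adjusted p = 0.936) and rose without KO LPS array 2 (median 0.27, adjusted p = 0.0371, and adjusted p = 0.813 with an estimated correlation). Neutrophil markers, at a median of 3.06, were higher in the same KO arrays as the lists that fell.

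After LPS limma called 76 genes between the genotypes, 47 higher and 29 lower in KO, and 91 without KO LPS array 2. The count was 3, 2 and 6 without WT LPS array 1, 2 or 3, 42 without WT unstimulated array 2 and 358 without KO LPS array 3. It was 0 when limma was fitted to the LPS arrays alone, with 1637 genes under an unadjusted p of 0.05 and a smallest adjusted p of 0.0785. Klra8 and Klra9 alone among the named genes passed in every fit that left out 1 array. Leaving out KO LPS array 2 ended the calls of Lcn2 (adjusted p = 0.0526), Chil4 (0.0749), Igkv19-93 (0.0745), Vegfa (0.0699) and Xcr1 (0.10). Across the unstimulated and LPS comparisons 23 genes rose in both (0.0962 expected by chance) and 4 fell in both (0.0136 expected), with a correlation of 0.687 over all genes, although same-numbered arrays resembled each other and the comparisons were not independent.

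Averaged over both stimulations, KO arrays held more transcript of neutrophil and NK cell genes and of Acsl3, and less of Jchain, Mmp12 and Cxcl10. Lcn2 (5.19 ± 0.58, limma adjusted p = 0.000946), Ngp (5.0 ± 0.53, adjusted p = 0.000778) and Camp (4.99 ± 0.53, adjusted p = 0.000778) rose (n = 6 arrays per genotype). Each passed again when same-numbered arrays were averaged into pair means (adjusted p = 0.0480, 0.0402 and 0.0423 in that order). Chil3 rose by 4.93 ± 0.55 (adjusted p = 0.000946, 0.0480 from pair means) and Klra8 by 3.75 ± 0.26 (adjusted p = 3.22e-05, 0.0154 from pair means). Gzmb, which encodes a cytotoxic protease, rose by 2.23 ± 0.23 (adjusted p = 0.000778, 0.0356 from pair means). Acsl3, which activates long-chain fatty acids, rose by 1.14 ± 0.12 (adjusted p = 0.000778, 0.0204 from pair means), and Ly6c1 rose by 1.11 ± 0.16 (adjusted p = 0.00305, 0.0356 from pair means). Jchain fell by 3.54 ± 0.30 (adjusted p = 0.000178, 0.0154 from pair means) and Mmp12 by 2.00 ± 0.17 (adjusted p = 0.000178, 0.0169 from pair means). The interferon-induced chemokine gene Cxcl10 fell by 1.57 ± 0.19 (adjusted p = 0.00153, 0.0338 from pair means).

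Other genes passed in the averaged comparison but not from pair means. The neutrophil gene Stfa2l1 (4.21 ± 0.72, limma adjusted p = 0.0105, 0.141 from pair means) and the chitinase-like gene Chil4 (3.94 ± 0.48, adjusted p = 0.0015, 0.0545 from pair means) rose. Wfdc21 (3.92 ± 0.66, adjusted p = 0.010, 0.134 from pair means) and the granzyme gene Gzma (2.96 ± 0.39, adjusted p = 0.00234, 0.0691 from pair means) rose. The proposed miR-142 targets Tgfbr1 (0.97 ± 0.12, adjusted p = 0.0015, 0.0545 from pair means) and Wasl, an actin regulator (0.94 ± 0.19, adjusted p = 0.0242, 0.115 from pair means), rose. So did Adm (0.73 ± 0.11, adjusted p = 0.00463, 0.0813 from pair means) and Vegfa (0.65 ± 0.10, adjusted p = 0.00567, 0.0545 from pair means). The glucose transporter gene Slc2a1 rose by 0.69 ± 0.12 (adjusted p = 0.0138, 0.151 from pair means). The light chain genes Iglv1 (−2.11 ± 0.29, adjusted p = 0.00279, 0.0691 from pair means) and Igkv4-72 (−1.95 ± 0.32, adjusted p = 0.00793, 0.119 from pair means) fell. Igkv19-93 (−1.88 ± 0.29, adjusted p = 0.00558, 0.106 from pair means) and Igk-V21 (−1.69 ± 0.28, adjusted p = 0.00948, 0.0974 from pair means) fell with them. The epithelial-type transcription factor gene Ehf (−1.49 ± 0.19, adjusted p = 0.00205, 0.0691 from pair means) and the chemokine gene Ccl4 (−1.35 ± 0.19, adjusted p = 0.00355, 0.0691 from pair means) fell.

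In the averaged comparison neutrophil genes rose (median 3.13, camera adjusted p = 7.14e-21, adjusted p = 0.179 with an estimated correlation). Of 14 members 12 were higher, S100a8 (3.06 ± 0.58, adjusted p = 0.0176, 0.166 from pair means) among them, and 14 adjusted over the list alone. NK genes rose with 9 of 14 higher and 11 adjusted over the list alone (median 0.89, camera adjusted p = 2.34e-13, adjusted p = 0.0575 with an estimated correlation). Platelet genes (median 0.51, camera adjusted p = 6.31e-05, adjusted p = 0.481 with an estimated correlation) rose with Pf4 as 1 higher member (1.76 ± 0.42, adjusted p = 0.0488, 0.252 from pair means) and 3 adjusted over the list alone. Erythroid genes (median 0.71, camera adjusted p = 0.00141, adjusted p = 0.553 with an estimated correlation) rose with Car1 as 1 higher member (0.71 ± 0.14, adjusted p = 0.0242, 0.178 from pair means) and 1 adjusted over the list alone. NRF2 genes (median 0.17, camera adjusted p = 0.000994, adjusted p = 0.488 with an estimated correlation) rose with 2 higher members and 7 adjusted over the list alone. These 2 were Pgd (1.33 ± 0.28, adjusted p = 0.0274, 0.186 from pair means) and Gsr (1.03 ± 0.21, adjusted p = 0.0242, 0.186 from pair means). Neutrophil markers were higher in the same KO arrays as each of these groups.

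Proposed miR-142 targets rose in the averaged comparison with 2 of 26 members higher and 2 adjusted over the list alone (median 0.17, camera adjusted p = 0.00115, adjusted p = 0.103 with an estimated correlation). Fatty acid oxidation genes (median 0.15, camera adjusted p = 0.00436, adjusted p = 0.432 with an estimated correlation) rose with 3 higher members and 3 adjusted over the list alone. These were Acsl3, Cpt2 (0.58 ± 0.14, adjusted p = 0.0422, 0.151 from pair means) and Decr1 (0.46 ± 0.10, adjusted p = 0.0370, 0.119 from pair means), and without KO LPS array 2 the list median was 0.080. Oxidative phosphorylation genes (median 0.08, camera adjusted p = 0.00555, adjusted p = 0.643 with an estimated correlation) rose with 0 members past the threshold. Hypoxia genes (median 0.11, camera adjusted p = 0.0153, adjusted p = 0.226 with an estimated correlation) rose with 3 higher members, and 7 higher and 2 lower adjusted over the list alone. Glycolysis genes (median 0.09, adjusted p = 0.247, and a median of 0.19 without KO LPS array 2) did not pass, with Slc2a1 higher and Pfkp lower (−0.47 ± 0.08, adjusted p = 0.0138, 0.0956 from pair means). TCA cycle genes (median 0.09, adjusted p = 0.109), actin cytoskeleton genes (0.01, adjusted p = 0.793) and cell cycle genes (0.09, adjusted p = 0.772, and −0.0069 without KO LPS array 2) did not pass. Cpt1a (0.46, adjusted p = 0.225), E2f7 (0.09, adjusted p = 0.679) and E2f8 (0.58, adjusted p = 0.389, and 0.25 without that array) did not pass either. Neutrophil markers were higher in the same KO arrays as each of the lists that rose here.

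Inflammatory cytokine genes fell in the averaged comparison (median −0.19, camera adjusted p = 0.00205, adjusted p = 0.229 with an estimated correlation). Of its members 4 were lower, Ccl22 (−1.19 ± 0.23, adjusted p = 0.0207, 0.173 from pair means) among them, and 9 adjusted over the list alone. Cholesterol synthesis genes (median −0.18, camera adjusted p = 0.00436, adjusted p = 0.362 with an estimated correlation) fell. Cyp51 was the 1 lower member, over all genes (−0.43 ± 0.07, adjusted p = 0.00948, 0.119 from pair means) and adjusted over the list alone. The cDC1 list (median −0.18, camera adjusted p = 0.0164, adjusted p = 0.481 with an estimated correlation) fell with 3 lower members and 4 adjusted over the list alone. These 3 were Xcr1 (−0.54 ± 0.11, adjusted p = 0.0219, 0.0712 from pair means), Cd8a (−0.53 ± 0.12, adjusted p = 0.0459, 0.214 from pair means) and Wdfy4 (−0.40 ± 0.07, adjusted p = 0.0122, 0.108 from pair means). The cDC2 list (median −0.16, camera adjusted p = 0.0342, adjusted p = 0.576 with an estimated correlation) fell with 3 lower members, and 1 higher and 4 lower adjusted over the list alone. The lectin genes Cd209a (−1.07 ± 0.25, adjusted p = 0.0418, 0.166 from pair means) and Cd209d (−0.76 ± 0.14, adjusted p = 0.0146, 0.0691 from pair means) fell, and so did Cd4 (−0.64 ± 0.12, adjusted p = 0.0171, 0.158 from pair means). Without KO LPS array 2 the cDC2 list did not pass (median −0.079, adjusted p = 0.176). Neutrophil markers, at a median of 3.13, were higher in the same KO arrays as each of these lists and as the MHC class I, DC maturation and interferon lists.

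MHC class I genes (median −0.17, camera adjusted p = 0.0304, adjusted p = 0.60 with an estimated correlation) fell in the averaged comparison with 0 members past the threshold. They did not pass without KO LPS array 2 (median −0.074, adjusted p = 0.134). DC maturation genes (median −0.27, camera adjusted p = 0.0459, adjusted p = 0.836 with an estimated correlation) fell with 2 lower members, and 1 higher and 5 lower adjusted over the list alone. Ccl22 and Tnfsf9 (−0.72 ± 0.15, adjusted p = 0.0234, 0.151 from pair means) were the 2. The list did not pass without KO LPS array 2 (median −0.075, adjusted p = 0.160) or from pair means (adjusted p = 0.0693). Type I interferon genes (median −0.18, camera adjusted p = 0.0466, adjusted p = 0.60 with an estimated correlation) fell with 3 lower and 1 higher member, and 3 higher and 6 lower adjusted over the list alone. Cxcl10, Ifih1 (−1.13 ± 0.20, adjusted p = 0.0138, 0.0928 from pair means) and Ifit1 (−1.13 ± 0.25, adjusted p = 0.0365, 0.154 from pair means) fell, and Gbp3 rose (0.95, adjusted p = 0.0327, 0.154 from pair means). The interferon list did not pass without KO LPS array 2 (adjusted p = 0.0501). The macrophage and monocyte list (median 0.16, adjusted p = 0.0843) did not pass, and rose without that array (median 0.30, adjusted p = 0.0210, and adjusted p = 0.813 with an estimated correlation). NF-kB feedback genes (median −0.20, adjusted p = 0.0678) did not pass, although Zc3h12a, an RNA-degrading brake on inflammation, rose by 0.45 ± 0.10 (adjusted p = 0.0363, 0.210 from pair means). Immediate early genes (median −0.18, adjusted p = 0.120, and a median of 0.018 without KO LPS array 2) did not pass, although Egr2 fell by 0.63 ± 0.11 (adjusted p = 0.0149, 0.103 from pair means). The B cell list did not pass (median 0.02, mean −0.21, adjusted p = 0.871, and a median of 0.33 without KO LPS array 2), with Jchain lower and Ms4a1, which encodes CD20, higher (0.87 ± 0.15, adjusted p = 0.010, 0.124 from pair means). Plasmacytoid DC genes (median 0.02, adjusted p = 0.742) did not pass, although Cox6a2 rose by 0.36 ± 0.08 (adjusted p = 0.0321, 0.204 from pair means). Il6 (0.47, adjusted p = 0.314) and Il12b (−0.26, adjusted p = 0.257) did not pass, with 0.26 and −0.17 without KO LPS array 2, and Il6 passed without KO LPS array 3 (0.67, adjusted p = 0.0422).

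The averaged comparison called 448 genes with limma, 298 higher and 150 lower in KO. It called 284 when the same-numbered arrays entered as a random block, and 41, 32 higher and 9 lower, when each pair was averaged into 1 value, and all 41 were among the 448. The count was 278, 253 and 220 without WT unstimulated array 1, 2 or 3, and 232, 211 and 197 without WT LPS array 1, 2 or 3. It was 186 and 203 without KO unstimulated array 1 or 2, 826 without KO LPS array 3 and 633 without KO LPS array 2, which ended the call of Cpt2 (adjusted p = 0.0503). Of the 48 named and called genes 32 passed in every fit that left out 1 array.

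**Figure D4:**
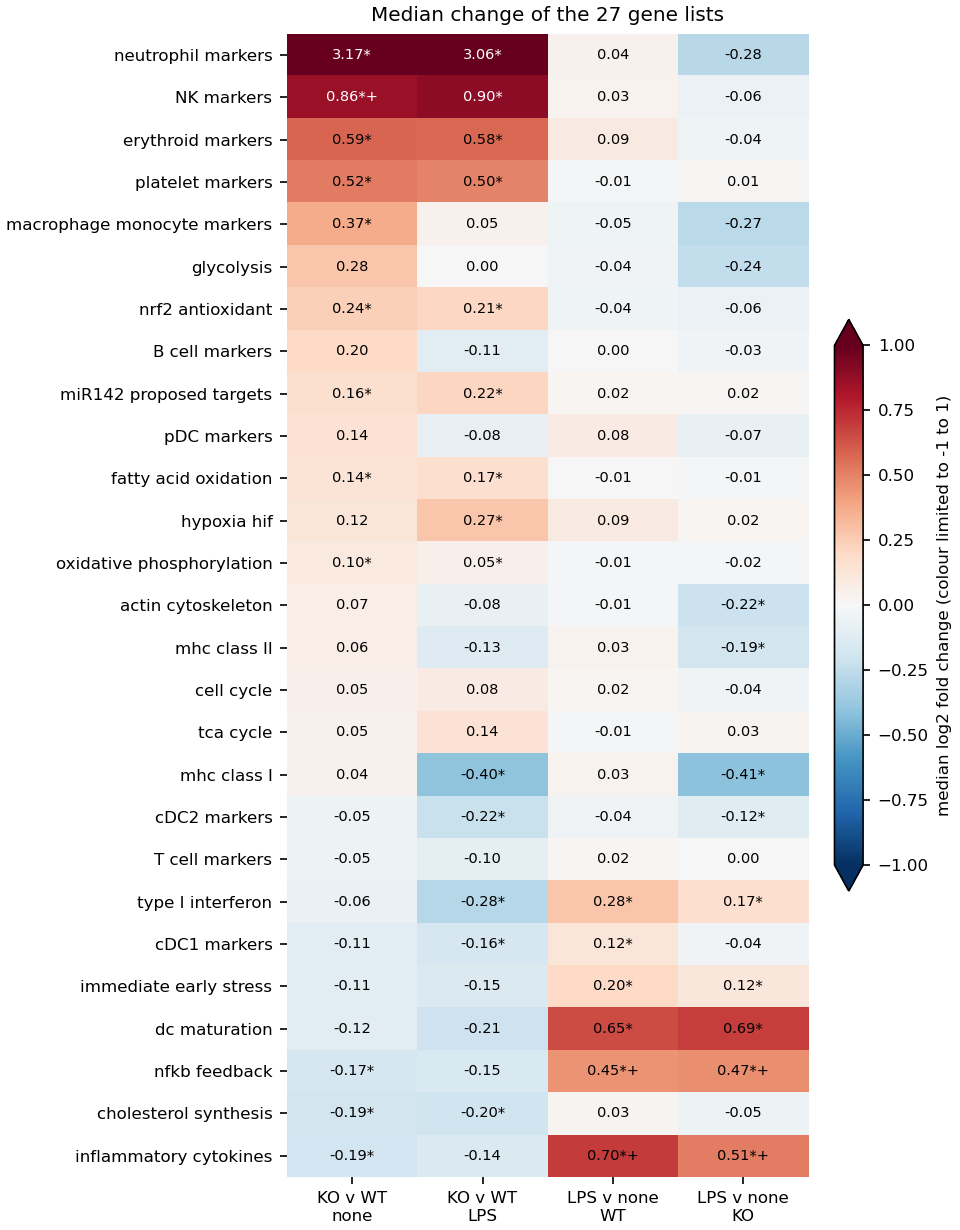
Median log2 fold change of 27 gene lists in 4 comparisons; a star marks camera adjusted p under 0.05 and a plus sign the same with an estimated correlation.

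In WT cells LPS raised cytokine, interferon-induced and maturation genes. Il12b, which encodes the p40 chain of interleukin 12, rose by 1.91 ± 0.16 (n = 3 arrays per group, limma adjusted p = 0.000503), and Il6 by 2.33 ± 0.31 (adjusted p = 0.00861). Tnf (1.40 ± 0.17, adjusted p = 0.00554) and Ifnb1 (1.84 ± 0.23, adjusted p = 0.00644) rose, as did the interferon-induced genes Ifit1 (2.62 ± 0.36, adjusted p = 0.0098) and Ifit2 (2.20 ± 0.36, adjusted p = 0.0444). The T cell costimulator gene Tnfsf9 (1.94 ± 0.21, adjusted p = 0.00303), the activation antigen gene Cd69 (1.92 ± 0.23, adjusted p = 0.00554) and Marcksl1 (1.10 ± 0.17, adjusted p = 0.0312) rose. The NF-kB feedback genes Nfkbiz (1.29 ± 0.15, adjusted p = 0.00554) and Tnfaip3 (0.96 ± 0.12, adjusted p = 0.00644) rose with them. Cpt1a (−0.37), E2f7 (0.09) and E2f8 (−0.04) did not pass (adjusted p = 1.00 for each).

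By list, LPS raised inflammatory cytokine genes in WT with 3 of 30 members higher and 15 adjusted over the list alone (median 0.70, camera adjusted p = 1.66e-24, adjusted p = 0.00323 with an estimated correlation). NF-kB feedback genes rose with 2 of 23 higher and 11 adjusted over the list alone (median 0.45, camera adjusted p = 7.14e-21, adjusted p = 0.0419 with an estimated correlation). Type I interferon genes rose with 2 of 28 higher and 10 adjusted over the list alone (median 0.28, camera adjusted p = 1.88e-15, adjusted p = 0.0589 with an estimated correlation). DC maturation genes rose with 2 of 21 higher and 10 adjusted over the list alone (median 0.65, camera adjusted p = 2.61e-18, adjusted p = 0.187 with an estimated correlation). The cDC1 list (median 0.12, camera adjusted p = 0.0333, adjusted p = 0.492 with an estimated correlation) rose with 0 members past the threshold and 1 higher adjusted over the list alone. Immediate early genes (median 0.20, camera adjusted p = 0.00375, adjusted p = 0.362 with an estimated correlation) rose with 0 members past the threshold and 0 adjusted over the list alone. With same-numbered arrays blocked and an estimated correlation, cytokine, interferon and maturation genes passed (adjusted p = 0.0340 for each) and NF-kB genes did not (adjusted p = 0.0670). Neutrophil (median 0.04, adjusted p = 0.981) and NK genes (0.03, adjusted p = 0.855) did not pass.

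LPS called 20 genes in WT with limma, all higher, and 67 without KO LPS array 2, which lies outside the comparison and acts through the shared variance. The count was 8 without WT unstimulated array 1 or 2, and 10 and 4 without WT LPS array 1 or 3. It was 75, 73 higher and 2 lower, with same-numbered arrays blocked within genotype, and 48 with a random block. Cd69, Il12b and Tnfsf9 passed in every fit that left out 1 array.

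In KO cells LPS raised the same classes of genes. Il6 rose by 3.04 ± 0.31 (n = 3 arrays per group, limma adjusted p = 0.000854) and Il12b by 1.65 ± 0.16 (adjusted p = 0.000673). Il10, which encodes an anti-inflammatory cytokine, rose by 2.32 ± 0.30 (adjusted p = 0.00442) and the neutrophil attractant gene Cxcl1 by 2.44 ± 0.29 (adjusted p = 0.00253). The interferon-induced genes Ifit1 (2.93 ± 0.36, adjusted p = 0.00253), Oasl1 (2.53 ± 0.34, adjusted p = 0.00462) and Ifih1 (2.44 ± 0.29, adjusted p = 0.00225) rose, and so did Ifit2 (2.35 ± 0.36, adjusted p = 0.0129) and Cxcl10 (2.35 ± 0.28, adjusted p = 0.00225). Tnfsf9 (2.27 ± 0.21, adjusted p = 0.000673), Cd40 (1.32 ± 0.21, adjusted p = 0.0148) and Ccl22 (1.78 ± 0.33, adjusted p = 0.0402) rose. Nfkbiz (1.81 ± 0.15, adjusted p = 0.000673), Tnfaip3 (1.19 ± 0.12, adjusted p = 0.000854), Zc3h12a (0.97 ± 0.14, adjusted p = 0.00862) and Adm (1.09 ± 0.16, adjusted p = 0.00758) rose too. The lymphoid egress receptor gene S1pr1 (−1.31 ± 0.25, adjusted p = 0.0476) and Pip5k1c (−0.89 ± 0.16, adjusted p = 0.0369) fell. Id3 (−0.88 ± 0.15, adjusted p = 0.0258), Ssna1 (−0.81 ± 0.12, adjusted p = 0.00862) and Map3k20 (−0.61 ± 0.11, adjusted p = 0.0402) fell. Pltp, a lipid transfer gene, fell by 0.86 ± 0.15 (adjusted p = 0.0265) and did not pass with same-numbered arrays blocked (adjusted p = 0.0509). Cpt1a (−0.06, adjusted p = 0.973, and −0.26 without KO LPS array 2), E2f7 (−0.0039, adjusted p = 0.997, and −0.087 without it) and E2f8 (0.65, adjusted p = 0.694, and −0.0033 without KO LPS array 2) did not pass.

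By list, LPS raised inflammatory cytokine genes in KO with 11 of 30 members higher and 15 adjusted over the list alone (median 0.51, camera adjusted p = 3.13e-24, adjusted p = 0.00323 with an estimated correlation). NF-kB feedback genes rose with 7 of 23 higher and 13 adjusted over the list alone (median 0.47, camera adjusted p = 4.69e-19, adjusted p = 0.0426 with an estimated correlation). Type I interferon genes rose with 5 of 28 higher, and 8 higher and 1 lower adjusted over the list alone (median 0.17, camera adjusted p = 3.22e-06, adjusted p = 0.241 with an estimated correlation). DC maturation genes rose with 4 of 21 higher and 10 adjusted over the list alone (median 0.69, camera adjusted p = 1.17e-11, adjusted p = 0.362 with an estimated correlation). Immediate early genes rose with 0 of 19 past the threshold and 3 higher adjusted over the list alone (median 0.12, camera adjusted p = 0.00436, adjusted p = 0.362 with an estimated correlation), and their median was 0.17 without KO LPS array 2. With pairs blocked the NF-kB list did not pass with an estimated correlation (adjusted p = 0.0834), and the cytokine list did (adjusted p = 0.0340).

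Antigen presentation genes fell in KO after LPS, with 0 members past the threshold in any of the lists. MHC class I genes had a median of −0.41 (camera adjusted p = 0.00193, adjusted p = 0.488 with an estimated correlation) and MHC class II genes −0.19 (camera adjusted p = 0.0178, adjusted p = 0.553 with an estimated correlation). Without KO LPS array 2 neither list passed (medians −0.16 and −0.045, adjusted p = 0.0508 and 0.465). The cDC2 list (median −0.12, camera adjusted p = 0.0459, adjusted p = 0.584 with an estimated correlation) fell and did not pass without that array (adjusted p = 0.996). Actin cytoskeleton genes fell (median −0.22, camera adjusted p = 0.00678, adjusted p = 0.488 with an estimated correlation), and their median was −0.11 without it. The 3' to middle gap of Gapdh was 3.04 on KO LPS array 2. With same-numbered arrays blocked, glycolysis (median −0.24, adjusted p = 0.0441), macrophage (−0.27, adjusted p = 0.0169) and neutrophil genes (−0.28, adjusted p = 0.00128) fell, while without the block they did not pass (adjusted p = 0.0882, 0.0689 and 0.493). With the block none of the 3 passed with an estimated correlation (adjusted p = 0.594, 0.616 and 0.517). Unblocked and without KO LPS array 2, the neutrophil list fell (median −0.57, adjusted p = 0.0371, and adjusted p = 0.820 with an estimated correlation).

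LPS called 67 genes in KO with limma, 61 higher and 6 lower, and 98 without KO LPS array 2, which ended the calls of S1pr1 (adjusted p = 0.0951), Pip5k1c (0.0616) and Map3k20 (0.0539). Of the 22 named and called genes 13 passed in every fit that left out 1 array. The count was 41 and 37 without KO unstimulated array 1 or 2, 148, 123 higher and 25 lower, with same-numbered arrays blocked within genotype, and 135 with a random block. Of the 20 genes called in WT, 16 were called in KO (0.0714 expected by chance), and the fold changes correlated at 0.390 over all genes. Across both genotypes 71 genes were called, 16 in both, 4 in WT alone and 51 in KO alone, and all 71 moved in the same direction in both.

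**Figure D5:**
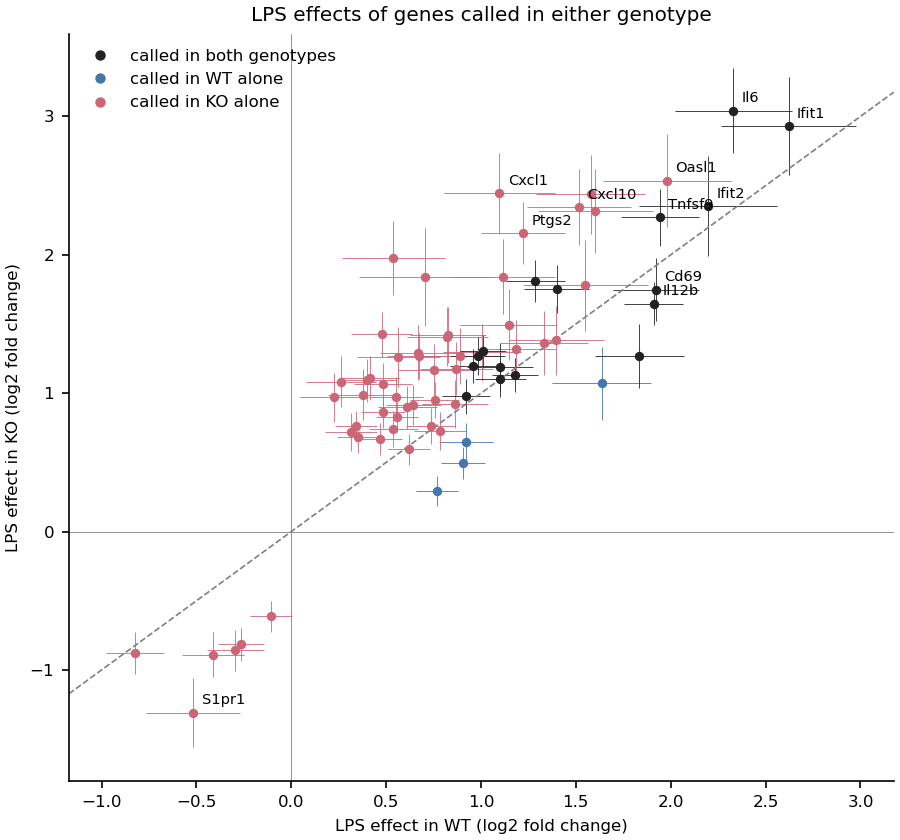
LPS effect in WT against KO for the 71 genes called in either genotype, with SE bars and the line of equality.

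No gene passed for a difference between the LPS effects of KO and WT. Cxcl1 differed by 1.35 ± 0.42 (95% interval 0.44 to 2.25, limma adjusted p = 0.969), Cxcl10 by 0.83 ± 0.39 (−0.02 to 1.68) and Il6 by 0.71 ± 0.44 (−0.24 to 1.66), as KO minus WT with n = 3 arrays per group. Cxcl1 started lower in KO (2.83 to 3.24 unstimulated, against 4.30 to 5.25 in WT) and reached 5.32 to 5.68 after LPS, against 5.31 to 6.41. Cxcl10 remained lower in KO after LPS (6.54 to 7.28, against 8.11 to 8.17 in WT). Nfkbiz differed by 0.52 ± 0.22 (0.05 to 0.99), Tnf by 0.35 ± 0.24 (−0.17 to 0.88) and Il12b by −0.26 ± 0.22 (−0.74 to 0.22). Leaving out KO LPS array 2 brought Il6 to 0.30 and Il12b to −0.081, and leaving out KO LPS array 3 instead brought them to 1.11 and −0.37. Cpt1a (0.31 ± 0.36), E2f8 (0.69 ± 0.62) and E2f7 (−0.09 ± 0.18, adjusted p = 0.974) did not pass, with 0.10, 0.036 and −0.18 without KO LPS array 2. Over the 20 genes called in WT, the LPS effect was larger in KO for 12 and smaller for 8, with a median ratio of 1.07, and 0.998 without KO LPS array 2.

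By list, the LPS effect on inflammatory cytokine genes was larger in KO (median difference 0.16, camera adjusted p = 0.0137, adjusted p = 0.362 with an estimated correlation, 0.000961 with same-numbered arrays blocked). Median and test ran apart within genotypes, since the list's median LPS effect was 0.70 in WT and 0.51 in KO (0.69 in KO without KO LPS array 2). By pair the list median rose by 0.62 to 0.87 in WT and by 0.92, 0.31 and 1.07 in KO. These genes were lower in unstimulated KO arrays (median −0.19), which enter this difference as well. For MHC class I genes the LPS effect was lower in KO (median difference −0.42, camera adjusted p = 0.000994, adjusted p = 0.481 with an estimated correlation). Their median LPS effect was 0.03 in WT and −0.41 in KO, a fall in KO where WT hardly moved. The LPS effect was also lower in KO for MHC class II genes (−0.27, camera adjusted p = 0.0458, adjusted p = 0.584 with an estimated correlation) and actin cytoskeleton genes (−0.19, camera adjusted p = 0.0277, adjusted p = 0.575 with an estimated correlation). Their medians were 0.03 in WT and −0.19 in KO for MHC class II, and −0.01 and −0.22 for actin genes. Without KO LPS array 2 the MHC class I median was −0.15 (adjusted p = 0.017) and MHC class II did not pass (median −0.066, adjusted p = 0.485), and the actin cytoskeleton median was −0.13. NF-kB feedback genes (median 0.21, adjusted p = 9.17e-05) and B cell genes (median 0.23, adjusted p = 0.0371) then passed with a larger effect in KO, but not with an estimated correlation (adjusted p = 0.375 and 0.813). With same-numbered arrays blocked the neutrophil list also passed (median −0.33, adjusted p = 0.000845, against 0.585 without the block), but not with an estimated correlation (adjusted p = 0.516). Its median was −0.76 without KO LPS array 2.

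The difference count was 0 by limma, with 639 genes under an unadjusted p of 0.05 and a smallest adjusted p of 0.969. It was 0 in every fit that left out 1 array and 0 with same-numbered arrays blocked within genotype. With that block and without KO LPS array 2 it was 1, Cxcl1 (1.36 ± 0.16, adjusted p = 0.0294), which started lower in unstimulated KO arrays. In the self-test, with 200 changed genes per run, 5.97%, 61.3% and 98.0% of shifts of 0.5, 1 and 2 were recovered for this difference. In the reported fit some differences over 1 did not pass, such as Il1a (1.44 ± 0.38) and Cxcl1 (1.35 ± 0.42, limma adjusted p = 0.969 for each). The self-test shares therefore need not hold here. A gene-level difference under 1 was often out of reach, and some over 1 may have been missed as well.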

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

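The RNA quality test of the array that stood apart was chosen only after the result was seen, and the test for a wrong label was set before.

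Array 2 of the LPS-treated KO group had a mean correlation of 0.947 with the other 11 arrays, and the MHC class I and class II lists were lower on it than on any other array. A mislabelled sample was argued against, because on at least 90% of the genes called between genotypes and by LPS the array lay nearer to its labelled group. Lower RNA quality is a candidate explanation: the 3' to middle gap of Gapdh was 3.04 on this array against at most 1.86 on the others, and WT-Ovation Pico primes partly from the 3' end. No biological explanation was tested, since no other array shared its genotype, stimulation and gap.

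Lists whose LPS effect differed between KO and WT in a direct test of the difference were inflammatory cytokine genes (median difference 0.16), MHC class I genes (−0.42), MHC class II genes (−0.27) and actin cytoskeleton genes (−0.19). With an estimated correlation none of these 4 passed (adjusted p = 0.362, 0.481, 0.584 and 0.575). Without KO LPS array 2 the MHC class I median was −0.15 (adjusted p = 0.017) and the MHC class II median −0.07 (adjusted p = 0.485), and the actin cytoskeleton median was −0.13 (adjusted p = 0.0274). The cytokine median was 0.17 without that array (adjusted p = 0.00121), and since these genes were lower in unstimulated KO arrays (median −0.19), the same 3 arrays enter both results.

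Among probe sets without a single gene symbol, outside the gene tests, 219 of 16139 were called between KO and WT averaged over both stimulations, 115 higher and 104 lower, and 15 were called from pair means. Their genes were not analysed here.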

How the results depend on the processing

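The random block, pair means, list tests by pair and fits combining these or an estimated correlation with leaving out KO LPS array 2 were tests chosen only after results were seen. Counts are given in the order KO versus WT unstimulated, KO versus WT with LPS, LPS in WT, LPS in KO, averaged and difference, with 43, 76, 20, 67, 448 and 0 as reported. A threshold of adjusted p under 0.10 gave 79, 190, 40, 119 and 864, and a block by array number over all arrays 170, 280, 53, 111 and 878. Array weights gave 148 unstimulated, 54 and 105 for LPS in WT and KO and 728 averaged. Fits to the groups of a contrast alone gave 84, 0 (by limma, with 1637 under an unadjusted p of 0.05), 56 and 13 for the first 4. LPS in WT called 34 without the 50% of genes with the lowest means and 31 from the mean of probe sets, and a 1.5-fold minimum left 278 averaged. The block within genotype gave 75 and 148 for LPS in WT and KO and the random block 48, 135 and 284 for these and the averaged comparison. Without KO LPS array 2 these were 219, 182 and 1 (difference) with the block within genotype, and 195 (unstimulated), 116 and 142 with the random block. Pair means gave 41 averaged. Leaving out 1 array gave 5 to 166, 2 to 358, 4 to 67, 37 to 98, 186 to 826 and 0 to 0. The cause of these moves was not tested. Of 162 gene list tests 61 passed, 5 with an estimated correlation, 4 with it and without KO LPS array 2, 4 with it and pairs, and 16 by fry.

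Of the lists that passed 1 turned direction, and of the named genes E2f7, E2f8, Cpt1a and Il6. Among lists that did not pass, medians near 0 such as glycolysis between genotypes after LPS changed sign under scaling, and others, such as immediate early genes averaged, without KO LPS array 2. The cDC2 list for LPS in KO had adjusted p = 0.996 without KO LPS array 2, and 0.999 with an estimated correlation as well. E2f7 with LPS in KO was 0.0040 after quantile normalisation, 0.029 centred and 0.025 blocked without that array, and −0.096 to 0.11 leaving out 1 array. E2f8 with LPS in WT was 0.034 from the mean of probe sets, and −0.25 to 0.10 leaving out 1. E2f7 between genotypes with LPS was −0.012 with array weights and −0.014 with the random block without KO LPS array 2, and −0.042 to 0.15 leaving out 1. Cpt1a with LPS in KO was 0.012 blocked without that array, and −0.26 to 0.22 leaving out 1. Leaving out 1 array gave −0.013 to 0.23 for Il6 between unstimulated genotypes, −0.0033 to 1.04 for E2f8 with LPS in KO and −0.19 to 0.018 for the difference of E2f7. None of these genes was called in the comparison listed for it here with all 12 arrays. Over the alternatives other than leaving out 1 array alone, named genes gave the same call 1957 times, a lost call 162 times and a turned direction 7 times. For lists that passed these counts were 229, 205 and 2, with the tests without KO LPS array 2 included. Apart from Pltp and the lists named in the report, blocking by pair changed no other call of a named gene or list for LPS or the difference in the reported tests. Of named genes, 4 of 19 unstimulated, 2 of 22 with LPS, 3 of 11 for LPS in WT, 13 of 22 for LPS in KO and 32 of 48 averaged passed without any 1 array, and 11 of 48 averaged from pair means. With 3 arrays against 3 the 10 splits are too few for a share under 0.05. The real and highest other counts were 43 and 0, 76 and 0, 20 and 0, 67 and 4, 448 and 0 (pairs) and 0 and 0 for the difference, where all 10 splits gave 0 by limma (639 genes under an unadjusted p of 0.05), and in every other comparison the real split was the 1 with a count as large. In KO the 3 other splits that parted all 3 pairs called 0. The planned tests on genes with miR-142 seed sites were not run.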

Other observations

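The neutrophil and NK cell tests and the LPS ratio test were chosen only after the result was seen, as were the gene families, and the test around Mir142 was set before.

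Some genes of immunoglobulin chains and of the Klra receptors passed in the averaged comparison, and neither family was tested as a set. Of 16 measured immunoglobulin chain genes 7 fell in KO (median −0.58, and −0.45 without KO LPS array 2), among them Igkv15-103 (−1.40) and Ighv6-6 (−1.17), and 0 of the 7 passed from pair means (adjusted p = 0.145 and 0.220 for these). Of 8 measured Klra genes 4 rose (Klra1, Klra7, Klra8 and Klra9, median 0.77, and 0.54 without that array), of which Klra1 and Klra7 did not pass from pair means (adjusted p = 0.214 and 0.151). Neither family's median in the averaged comparison changed sign under the scaling alternatives. Among genes that passed from pair means as well, the myelin gene Pmp22 (1.84) and the lymphocyte protease gene Ctsw (1.55) rose. So did Tnfrsf13c (0.83), a TNF receptor family gene of B cells. Among the same genes the transcription factor gene Stat4 (−1.30) and Anxa6 (−0.71) fell.

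Neutrophil transcripts were higher in every KO array. Relative to the mean of the WT arrays, list medians were 4.15, 4.33 and 1.65 unstimulated and 3.71, 3.87 and 1.62 after LPS. Of 14 markers 11 had every KO array above every WT array (chance gives at most 5% of genes with same-numbered arrays as pairs). These markers move together on the same arrays, so the 11 are not separate observations. A lower share of DCs alone was tested on the T cell list, which did not rise alike. It lay below the WT mean on 5 of the 6 KO arrays, at −0.16 or above. On the other it lay above by 0.0115 of the neutrophil change. Other lists lay above the WT mean on each of the 6 KO arrays, NK by 0.44 to 1.16, erythroid by 0.22 to 0.87 and platelet by 0.04 to 1.07. The B cell list went both ways. The T cell list cannot stand for every cell type, so a lower share of DCs was left undecided. Neutrophils carried through the positive selection are a candidate explanation. The 12 called markers rose and fell together over the 6 KO arrays (median correlation 0.962, against −0.0109 for random sets). These arrays form 3 same-numbered pairs, and the correlation follows the lower values of pair 3. The markers were chosen as called on these arrays, and a shared change of expression within DCs could give the same correlation. The abundant S100a8 stood at 7.35 in WT and 10.20 in KO and S100a9 at 8.31 and 10.77, unstimulated. In WT arrays 9 of the 14 markers lay above the median gene (3.14), 0 are held by another list, and Elane (0.48) and Cxcr2 (1.56) did not pass. More neutrophils in KO spleens and expression by the DCs themselves were not tested.

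NK cell transcripts were higher in KO, with every KO array above every WT array for 8 of 14 markers. Chance gives this for at most 5% of genes with same-numbered arrays as pairs, but markers on the same arrays are not separate observations. Shared sequence of Klra probes alone was argued against, since 8 called markers lay outside that family. NK cells carried through the positive selection may account for Gzma, Gzmb and Eomes, but this and altered expression within DCs cannot be told apart. The median correlation of the 9 called markers over the 6 KO arrays was −0.163, and the KO arrays may vary too little in NK content to show one. The bar for this correlation to count against carried cells was set lower here than for neutrophils, and −0.163 lies under the neutrophil bar. Prf1 (−0.20), Klrk1 (−0.12) and Ccl5 (−0.11), which NK cells express, did not pass. In WT arrays 9 of the 14 markers lay above the median gene, and 1, Ccl5, is held by another list.

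Of the 200 measured genes nearest to Mir142, 9 were called in the averaged comparison (4.5%, 95% interval 2.08% to 8.37%, against 2.59% elsewhere, one-sided Fisher p = 0.0802), Mpo and Ccl4 among them, and 0 of the 200 passed from pair means, where 41 genes passed in all. DNA of another strain around the deleted gene cannot be told apart from other causes with so few called genes. Over the 20 genes called in WT, a weaker LPS effect in KO was argued against by a median ratio of 1.07 to WT (0.998 without KO LPS array 2). The ratio was 1.44 over the 67 genes called in KO (1.42 without it), so its size rests on which genotype's calls are used. It compares changes from each genotype's own unstimulated level and does not cover other genes or the levels reached after LPS. The median list effect in WT and KO was 0.70 and 0.51 for cytokine and 0.28 and 0.17 for interferon genes. For NF-kB feedback genes it was 0.45 and 0.47, and for DC maturation genes 0.65 and 0.69.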
